A study of Mus musculus with 2 samples.

How the data were processed

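The study measured polyadenylated RNA by sequencing in 2 mouse cell populations: E14TG2a embryonic stem cells in 2iLIF (mESC) and epiblast stem cells converted from 2iLIF cultures in vitro (cEpiSC), with 1 library each. Per the labels' protocols, total RNA was purified on columns, mRNA was captured on oligo(dT) beads and fragmented, cDNA was primed with random hexamers, dUTP was built into the second strand, and libraries were amplified by PCR and sequenced as DNA nanoballs on a BGI instrument with paired reads. The submitters' processing notes name HISAT2, Bowtie2, RSEM 1.3.1 and DESeq2 1.34.0 and the mouse build GRCm38.p6. The step each tool served, the gene annotation and any filters are not given in the sources used here. The chemistry keeps strand, but whether counting used it is not given, so reads of overlapping antisense genes may be mixed.

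For each library, per the file headers, the deposited table gives read counts, TPM and FPKM for 18032 genes. The deposited read counts are values of the kind called estimated counts, made by the authors without scaling, since 11.3% of genes in mESC and 11.9% in cEpiSC hold a value more than 0.005 from a whole number, as happens when reads are shared among similar loci. Such genes are named with that limit. The TPM columns, deposited by the authors, are scaled per kilobase to the same sum in each library. The FPKM columns, also deposited by the authors, are per kilobase and scaled to fragment totals, and sum to 543589 (mESC) and 590682 (cEpiSC). No column of another sample was present (0). Of the genes, 1148 had 0 counts in both libraries.

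Estimated counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 under R 4.3.3 (factors 0.975 for mESC and 1.03 for cEpiSC). The log2 ratio of cEpiSC over mESC used a prior count of 2. Genes at 1 CPM or more in at least 1 library (13243) were tested in the sense of being ranked: a gene was called higher or lower at 2-fold or more, by size alone. The design left no residual degrees of freedom, so no p-value was computed, and each call describes these libraries and not the conditions. Intervals of a ratio are exact conditional (Clopper-Pearson) 95% intervals of the ratio without the prior count, and fold values are also without it. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene with 0 counts in a library was set against a floor of 3 counts per library, which equals 0.155 CPM (mESC) or 0.147 CPM (cEpiSC). The fold written as at least a value takes the count of the other library as exact, so the 95% limit of the ratio nearest to no difference is smaller. The median interval half-width on the log2 scale was 0.64 for 3445 genes from 1 to 10 CPM, 0.17 for 7031 genes from 10 to 100 CPM and 0.07 for 2767 genes above that.

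Before the data were examined, 36 gene lists, 14 preset genes, the rule for naming genes, the size rule and the settings for repeat analyses were fixed. Named genes are the preset genes Rac1, Cdh1, Cdh2, Ctnnb1, Actb, Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Fgf5, Otx2 and Dnmt3b; in each list up to 4 tested members with the largest absolute log2 ratio among those at least 2-fold apart, or the 2 most abundant members where none was; and the 10 highest and 10 lowest ratios among genes at 10 CPM or more, without predicted genes (199 of these, of which 14 were higher and 15 lower). Other list members were named after their values were seen, to complete groups of 5 or fewer, or to give the lower genes of the Rac regulator list. For each list the median ratio is given with a 95% range from 1000 Poisson resamples of the counts, and with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. After a trend with length had been seen, percentiles were also computed with lists matched on transcript length or GC content (10 bins of either, within 5 of expression). Transcript length is the effective length implied by the deposited counts and FPKM, taken for each gene from the library with more counts. Where the libraries imply different lengths for a gene, the length used can therefore depend on the direction of its ratio. GC content came from the longest GENCODE vM21 transcript, found for 98.7% of tested genes. Coordinates, 1-based, are those of the gene in a RefSeq gene table of GRCm38.p6, joined by Entrez identifier (17913 of the listed genes, 99.3%). The list of mitochondrially encoded genes had no matched member and was not analysed here. The result of 1 other list and the values of 2 list members are not reported here.

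The analysis was repeated with size factors from DESeq2 1.42.0, library totals alone, no filter on low abundance, a filter at 5 CPM, prior counts of 0.5 and 5, and the deposited TPM and FPKM with a pseudocount of 1. Ratios centred on the median of each decile of transcript length or of GC content were added after seeing the data. Remaining computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

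The procedure was tested on simulated data. Counts for the 18032 genes were drawn from the observed means, with 100 genes changed 2.5-fold and 100 changed 4-fold. With counting noise alone 95% and 100% of these passed 2-fold, and 29 of 12765 unchanged genes did. With a biological coefficient of variation of 0.1 the shares were 86% and 99% with 48 of 12748 unchanged genes passing, and at 0.2 they were 69% and 98% with 378 of 12800. On 13243 genes the ratio interval covered the true ratio in 95.5% of cases. For the list percentile, the ratios were replaced by independent random values. With these, 10 of 200 unshifted lists fell outside percentiles 2.5 and 97.5. All 50 of 50 lists shifted by more than the standard deviation of those values lay above the upper edge. That check covers the calculation only, and not small shifts or lists whose genes vary together.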

Results

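Polyadenylated RNA was sequenced from mouse cells in 2 states of pluripotency, with 1 library for each state. The mESC library came from E14TG2a embryonic stem cells, given as wild type in the labels, grown in 2iLIF, a serum-free medium that holds cells in the naive or ground state of the early embryo's pluripotent tissue. It contains LIF at 100 units/ml, 1 µM of PD0325901, which blocks signalling through ERK, and 3 µM of CHIR99021, which inhibits GSK3 and so activates Wnt signalling. The cEpiSC library came from such cells after conversion in culture towards the primed state of the later epiblast. For this they were plated on fibronectin in 2iLIF, and 24 h later moved into N2B27 with 20 ng/ml of activin A and 12 ng/ml of FGF2, in which they stayed for 2 days. The libraries held 1.98e+07 estimated counts (mESC) and 2.00e+07 (cEpiSC), and 15666 and 16374 of the 18032 listed genes had at least 1 count. The 10 most abundant genes took 5.66% and 6.11% of the counts, led in both by the elongation factor gene Eef1a1 at 1.35% and 1.71%. With 1 library per state, no difference below has a replicate check and no p-value is given. The states also differ in medium, so effects of the medium and its inhibitors cannot be told apart from the change of state. Values are CPM, counts scaled to library size, with TMM factors. Levels are followed by the log2 ratio of cEpiSC over mESC, with its exact 95% interval in brackets, which covers counting error only.

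The comparison asks how the transcriptome of ground-state cells differs from that of cells after 2 days of conversion towards the primed state. Particular regard is given to Rac1, cadherins and the actin cytoskeleton, which the series title names. Of 13243 genes at 1 CPM or more in at least 1 library, 1796 were at least 2-fold higher in cEpiSC and 1225 at least 2-fold lower. At 4-fold the counts were 772 and 376. The counting interval lay wholly beyond 2-fold for 1212 of the higher and 840 of the lower genes. Among 9798 genes at 10 CPM or more in either library, 667 were higher and 780 lower, so the excess of higher genes lay among those at low abundance. Across the tested genes, which are not independent replicates, log2(CPM + 1) of the libraries had a Pearson correlation of 0.927.

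The genes with the highest ratios were mostly silent or near silent in mESC. Car4, a carbonic anhydrase, had 0 counts in mESC and 1011 in cEpiSC, at least 319-fold higher against a floor of 3 counts without counting error (lower 95% limit of the log2 ratio 8.01). Vrtn (0 and 521 counts, at least 164-fold, lower limit 7.06), the growth factor gene Fgf5 (0 and 276, at least 87.0-fold, lower limit 6.13) and the chemokine gene Cxcl12 (0 and 221, at least 69.7-fold, lower limit 5.81) were likewise absent from mESC. The transcription factor gene Myrf was 111-fold higher (21 and 2470 counts), the ERK phosphatase gene Dusp4 103-fold (15 and 1640) and Pou3f1, which encodes the POU factor Oct6, 90.9-fold (10 and 961). Ranked by the log2 ratio with its prior count, Cthrc1 (1 and 223 counts, 211-fold, log2 ratio 6.18 [5.23 to 13.03]), Selenop (8 and 503, 59.5-fold, 5.59 [4.90 to 7.11]) and Ndnf (4 and 298, 70.4-fold, 5.58 [4.77 to 8.02]) completed the 10 highest. At the other end stood the channel gene Trpm1 (843 and 3 counts, log2 ratio -7.47 [-10.50 to -6.66]), the serotonin receptor gene Htr5a (392 and 1, -7.09 [-14.00 to -6.21]) and the transcription factor gene Gata2 (342 and 1, -6.90 [-13.81 to -6.01]). Mal went from 239 counts to 0, at least 84.3-fold lower against the floor (upper 95% limit of the log2 ratio -6.09). Lcp1, S1pr1, Ly6a, Sp5, Cdx1 and Spic made up the rest of the 10 lowest. S1pr1, a sphingosine-1-phosphate receptor gene, had 420 and 3 counts (-6.46 [-9.49 to -5.65]), and Ly6a, which encodes the surface antigen Sca-1, had 395 and 5 (-5.89 [-8.02 to -5.15]).

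Genes of naive pluripotency were lower in cEpiSC and genes of the primed or formative state higher, while Pou5f1 and Sox2, central to both states, differed little. Pou5f1, which encodes Oct4 (Entrez 18999, chromosome 17, 35506032 to 35510777 in GRCm38.p6), stood at 841 CPM in mESC and 922 CPM in cEpiSC, a log2 ratio of 0.13 (0.10 to 0.16). Sox2 stood at 354 and 423 CPM (0.26 [0.21 to 0.31]). Nanog (Entrez 71950, chromosome 6, 122707489 to 122714633) was 1.90-fold lower at 1218 and 642 CPM (-0.92 [-0.96 to -0.89]), with counts partly shared with similar loci and so less certain than the interval says. Of the 22 naive genes, 12 were at least 2-fold lower, 2 higher and 8 within 2-fold. Klf4 (Entrez 16600, chromosome 4, 55527137 to 55532475) went from 313 to 80.2 CPM (-1.97 [-2.05 to -1.89]), Esrrb from 830 to 375 CPM (-1.15 [-1.19 to -1.11]) and Zfp42, also called Rex1, from 514 to 281 CPM (-0.87 [-0.92 to -0.82]). The differences were far larger for Spic (30.8 to 0.586 CPM, -5.49 [-6.68 to -4.90]), Jam2 (255 to 8.84 CPM, -4.83 [-5.07 to -4.63]), Tfcp2l1 (677 to 59.3 CPM, -3.51 [-3.60 to -3.43]) and Tbx3 (285 to 27.1 CPM, -3.39 [-3.53 to -3.27]). The 2 higher members were Gbx2 (5.27 to 13.3 CPM) and Nlrp4f (25.6 to 51.7 CPM). Nlrp4f, like most other list members outside the fixed naming rule, was named after its value was seen, to complete a group of 5 or fewer. The list's median log2 ratio was -1.12 (-1.17 to -1.07), below all 10000 random lists matched on expression.

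Of the 20 primed or formative genes, 14 were at least 2-fold higher, 1 lower (Krt19, 3.88 to 1.47 CPM) and 5 within 2-fold, with a median log2 ratio of 2.38 (2.24 to 2.497) that lay above all 10000 random lists. Fgf5 (Entrez 14176, chromosome 5, 98254184 to 98277033), a marker of the postimplantation epiblast, reached 13.5 CPM from 0 counts. Otx2 (Entrez 18424, chromosome 14, 48656781 to 48667644), a transcription factor of the exit from the naive state, was 6.73-fold higher (40.4 to 272 CPM, 2.75 [2.64 to 2.86]). Pou3f1 went from 0.517 to 47.0 CPM (6.25 [5.62 to 7.57]) and Sox11 from 2 to 126 counts (4.94 [4.01 to 8.96]). Fgf5 and Car4 had 0 counts in mESC, and the median was the same with both at their bound. The core list, of genes active in both states, was higher as well: 6 of 10 were at least 2-fold higher and none lower, with a median of 1.297 (1.24 to 1.341) above all random lists. Utf1 (100.3 to 710 CPM, 2.82 [2.75 to 2.89]), the adhesion molecule gene Epcam (43.2 to 218 CPM, 2.33 [2.23 to 2.44]), Dppa2 (51.9 to 169 CPM, 1.70 [1.60 to 1.80]) and Dppa4 (60.4 to 160.3 CPM, 1.41 [1.31 to 1.51]) led that list.

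**Figure D1:**
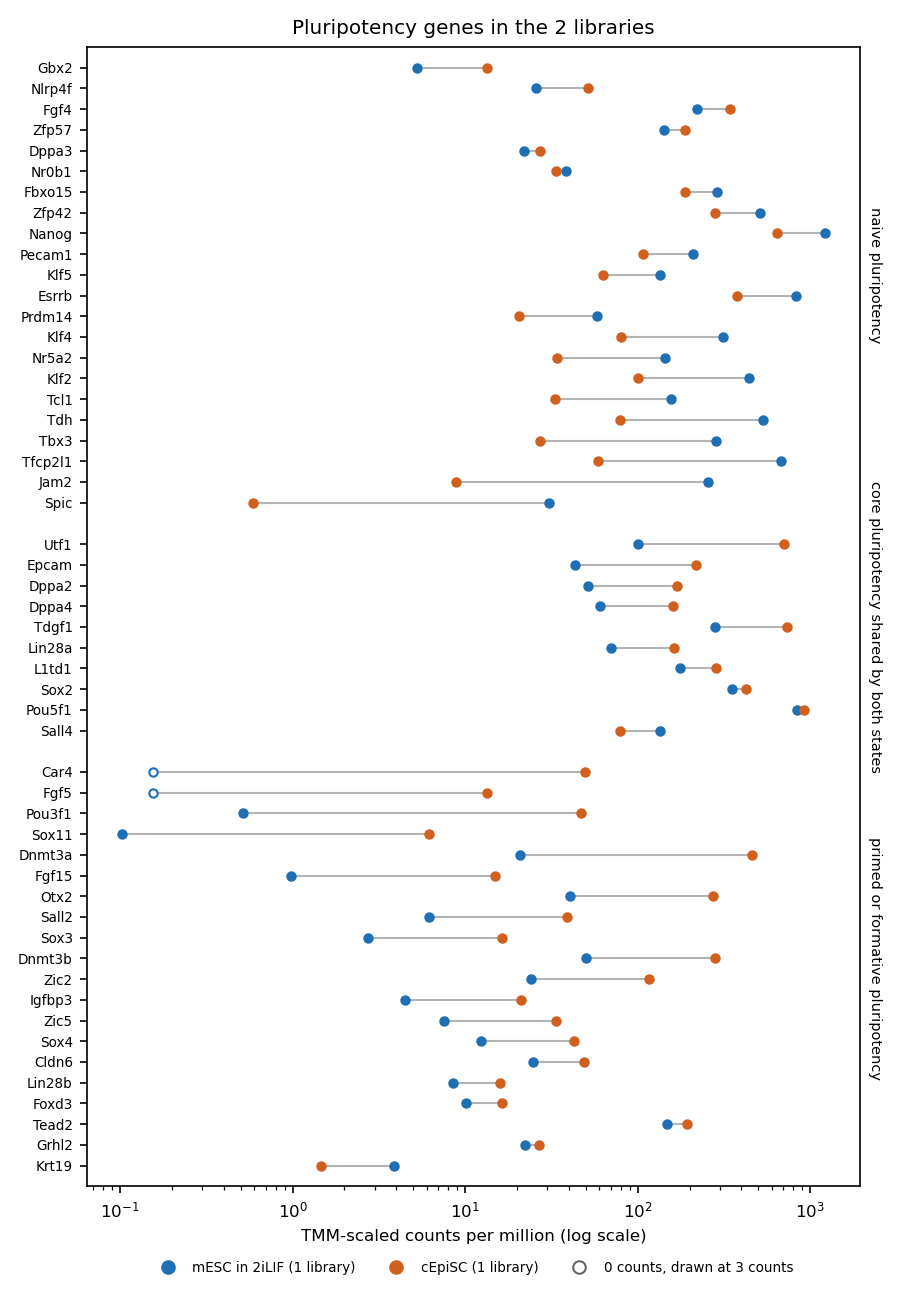
Each line joins a gene's level in the mESC library (blue) and the cEpiSC library (orange), as TMM-scaled CPM on a log axis, for tested members of 3 pluripotency lists, with open points for 0 counts drawn at the floor of 3 counts. In the naive list 12 of 22 genes were at least 2-fold lower in cEpiSC, and in the primed list 14 of 20 were at least 2-fold higher.

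Among the enzymes that write DNA methylation, the de novo group was higher. Dnmt3a went from 20.9 to 462 CPM (4.46 [4.32 to 4.61]), its cofactor gene Dnmt3l from 37.6 to 406 CPM (3.43 [3.32 to 3.54]) and Dnmt3b (Entrez 13436, chromosome 2, 153649411 to 153687730) from 50.4 to 280 CPM (2.47 [2.38 to 2.57]). Tet2, which encodes an enzyme that oxidises methylated cytosine, was lower at 87.6 and 42.5 CPM (-1.04 [-1.16 to -0.93]), but by less than 2-fold with library totals (-0.97), FPKM (-0.85) or centring on length (-0.72). The other 7 of the 11 listed genes stayed within 2-fold, and the list's median of 0.12 lay at percentile 90.2 of random lists, or was 0.24 at percentile 98.2 after centring on length. Germline genes known to be silenced by promoter methylation were not lower as a group: 6 of 16 were at least 2-fold higher, 2 lower and 8 within 2-fold, at a median of 0.50 (0.39 to 0.70) and percentile 99.8. Mael (5.74 to 36.1 CPM, 2.63), Tdrd1 (0.672 to 2.98 CPM, 2.00) and Tuba3b (10.5 to 36.2 CPM, 1.77, with shared reads) were among the higher, while Dazl went from 181 to 43.6 CPM (-2.05 [-2.16 to -1.95]) and Rpl10l from 106 to 51.8 CPM (-1.03 [-1.14 to -0.92]).

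The signalling lists below concern pathways that the 2 media act on directly, through inhibitors and LIF in mESC and activin A and FGF2 in cEpiSC. Their differences cannot be assigned to the state rather than the medium. The FGF and ERK list and the Nodal list had high medians, although in the Nodal list only 5 of 12 genes were at least 2-fold higher in cEpiSC. The medians of the Wnt and the LIF lists lay within the central 95% of random lists, except for Wnt with FPKM (percentile 2.28) and LIF after centring on length (2.14). Some members of the Wnt and LIF lists were nevertheless far lower, and the means of these lists were -0.86 and -0.85. Of 18 genes that respond to FGF and ERK, 11 were at least 2-fold higher in cEpiSC, none lower and 7 within 2-fold, with a median of 1.61 (1.28 to 2.00) above all random lists. These included feedback inhibitors of the pathway, namely Dusp4 (0.775 to 80.1 CPM, 6.52 [5.97 to 7.53]), Spry4 (1.76 to 66.7 CPM, 5.17 [4.76 to 5.78]) and Dusp6 (5.01 to 151 CPM, 4.89 [4.62 to 5.22]), and also Myc (2.12 to 28.5 CPM, 3.69 [3.29 to 4.25]). Of 12 genes that respond to Nodal and activin, 5 were higher, 1 lower and 6 within 2-fold, at a median of 0.71 (0.66 to 0.76) above all random lists. Lefty1, a secreted Nodal antagonist gene with partly shared reads, went from 13.4 to 184 CPM (3.77 [3.60 to 3.96]), Inhbb from 1.65 to 13.5 CPM (2.96) and Skil from 35.7 to 138 CPM (1.95). Tdgf1 was a further higher member (279.8 to 730.0 CPM) and Fst the lower (2.84 to 0.928 CPM). In the Wnt list 6 of 15 genes were lower, 2 higher and 7 within 2-fold, at a median of -0.32 (-0.42 to -0.26) and percentile 5.15. Sp5 (272 and 3 counts, -5.84 [-8.87 to -5.02]), Cdx1 (58.3 to 0.928 CPM, -5.83 [-6.71 to -5.32]) and Rnf43 (6.72 to 0.586 CPM, -3.31 [-4.51 to -2.66]), all known targets of beta-catenin, were lower. Lef1, which encodes a DNA-binding partner of beta-catenin, was higher at 0.465 and 14.4 CPM (4.68 [4.005 to 6.09]), as was Nkd2 (1.09 to 8.36 CPM). In the LIF and STAT3 list 4 of 12 genes were lower (Bcl3, 77.2 to 6.21 CPM, -3.61; Tfcp2l1; Klf4; and Stat3 itself, 139 to 68.9 CPM), 1 higher (Gbx2, 1.32) and 7 within 2-fold. That list's median was -0.42 (-0.60 to -0.36), at percentile 3.58. It shares 3 genes with the naive list.

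Rac1 transcript levels hardly differed, whereas the E-cadherin transcript was lower and the P-cadherin transcript higher in cEpiSC. Rac1, the small GTPase named in the series title (Entrez 19353, chromosome 5, 143505481 to 143528031), stood at 226 CPM in mESC and 216 CPM in cEpiSC. The log2 ratio of -0.06 (-0.12 to -0.00) became 0.01 when only library totals were used for scaling, and also 0.01 with FPKM. Cdh1, which encodes E-cadherin (Entrez 12550, chromosome 8, 106603350 to 106670247), was the most abundant cadherin transcript in both libraries and 1.76-fold lower in cEpiSC, at 1381 and 783 CPM (-0.82 [-0.85 to -0.79]). Cdh3, the neighbouring gene for P-cadherin (Entrez 12560, chromosome 8, 106510852 to 106556911), was 7.56-fold higher, at 16.4 and 124 CPM (2.91 [2.75 to 3.09]). Cdh2, which encodes N-cadherin (Entrez 12558, chromosome 18, 16588877 to 16809246), had 25 and 40 counts (0.56 [-0.16 to 1.38]), so a difference was not detectable at this depth. Of 31 listed cadherins 16 were tested, of which 4 were higher (Cdh3, Pcdh1 at 3.15 and 27.6 CPM, Pcdh8 with 3 and 76 counts, and Cdh15 with 6 and 146 counts), 4 lower (Dsg2, 180 to 65.7 CPM; Celsr1, 56.5 to 24.9 CPM; Pcdh19, 8.84 to 1.56 CPM; and Celsr3, 6.87 to 3.08 CPM) and 8 within 2-fold. After centring on length Celsr1 (-0.86) and Celsr3 (-0.82) were within 2-fold too. The cadherin median was -0.28 (-0.50 to -0.07), the mean 0.38, and the percentile 5.93, or 14.9 when random lists were also matched on transcript length. Without the low-abundance filter the cadherin median was 0.21.

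Among catenins and junction linkers 12 of 20 genes were below a log2 ratio of 0 and 8 above. Ctnnb1, which encodes beta-catenin, stood at 785 and 590 CPM (-0.41 [-0.45 to -0.38]). Of 20 such genes 2 were at least 2-fold higher, the plakophilin gene Pkp2 (33.0 to 84.7 CPM, 1.36 [1.23 to 1.49]) and Nectin4 (2.58 to 8.99 CPM, 1.76 [1.341 to 2.28]), 1 was lower, the delta-catenin gene Ctnnd2 (26.1 to 7.04 CPM, -1.88 [-2.17 to -1.62]), and 17 were within 2-fold. The median was -0.28 (-0.32 to -0.21), at percentile 6.96, or 26.6 with lists also matched on length, and the median was -0.048 after centring on length. Tight junction and apical polarity genes gave 5 higher, none lower and 18 within 2-fold, at a median of 0.11 (0.03 to 0.23) and percentile 88.6. The higher members were Cldn5 (9 and 147 counts, 3.69), the apical sialomucin gene Podxl (30.9 to 96.9 CPM, 1.65 [1.52 to 1.78]), Cgn (21.5 to 45.6 CPM, 1.08), Marveld3 (1.45 to 3.13 CPM, 1.06) and Cldn3 (9.30 to 18.96 CPM).

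Most genes of the machinery that builds actin networks lay within 2-fold, and a few differed by much more. Most of all 13243 tested genes also lay within 2-fold, with 1796 higher and 1225 lower. Lying within 2-fold thus does not mark the actin genes as unusually stable. The largest difference among the actin genes was that of Lcp1, which encodes the actin-bundling protein L-plastin: it went from 128 to 1.17 CPM, 109-fold lower (-6.65 [-7.41 to -6.19]). Actb, the cytoplasmic beta-actin gene (Entrez 11461, chromosome 5, 142903115 to 142907976), stood at 2797 and 2031 CPM (-0.46 [-0.48 to -0.44]), with part of its reads shared with similar loci. Of 29 actomyosin and bundling genes 6 were higher, 5 lower (among them Lcp1, Cnn2 at 80.0 and 18.8 CPM, Myh9 at 562 and 214 CPM and Fscn1 at 832 and 374 CPM) and 18 within 2-fold. The higher members included Vil1 (18 and 137 counts, 2.72 [2.13 to 3.64]), Tagln (2 and 43, 3.43 [2.40 to 7.44], with shared reads) and Cnn1 (2 and 25, 2.70 [1.56 to 6.69]). The median of this list was -0.24 (-0.38 to -0.13), at percentile 3.91. Of the 24 subunits and activators of the WAVE and Arp2/3 complexes, which nucleate branched actin downstream of Rac, 22 lay within 2-fold and none was lower by that much, but 16 were below 0 and the median of -0.34 (-0.38 to -0.29) lay at percentile 2.19, or 1.06 with lists also matched on length. Centring the ratios on GC content moved that percentile to 4.22. The 2 higher members were Actr3b (9.10 to 19.5 CPM, 1.10 [0.84 to 1.37]) and Cyfip2 (30.6 to 61.5 CPM, 1.005 [0.87 to 1.15]). Formins and the kinase genes listed with them had 3 lower, 1 higher and 13 within 2-fold, at a median of -0.49 (-0.57 to -0.42). That lay at percentile 0.63, at 5.22 with lists also matched on length, and at 0.71 after centring on length, with a median of -0.44. Fmnl1 went from 25.3 to 4.10 CPM (-2.59 [-2.97 to -2.29]), Cit from 89.5 to 37.0 CPM (-1.27 [-1.40 to -1.15]), Fmn1 from 19.5 to 8.36 CPM (-1.21 [-1.49 to -0.96]), and Fhod3 from 6.10 to 23.9 CPM (1.95 [1.68 to 2.27]).

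**Figure D2:**
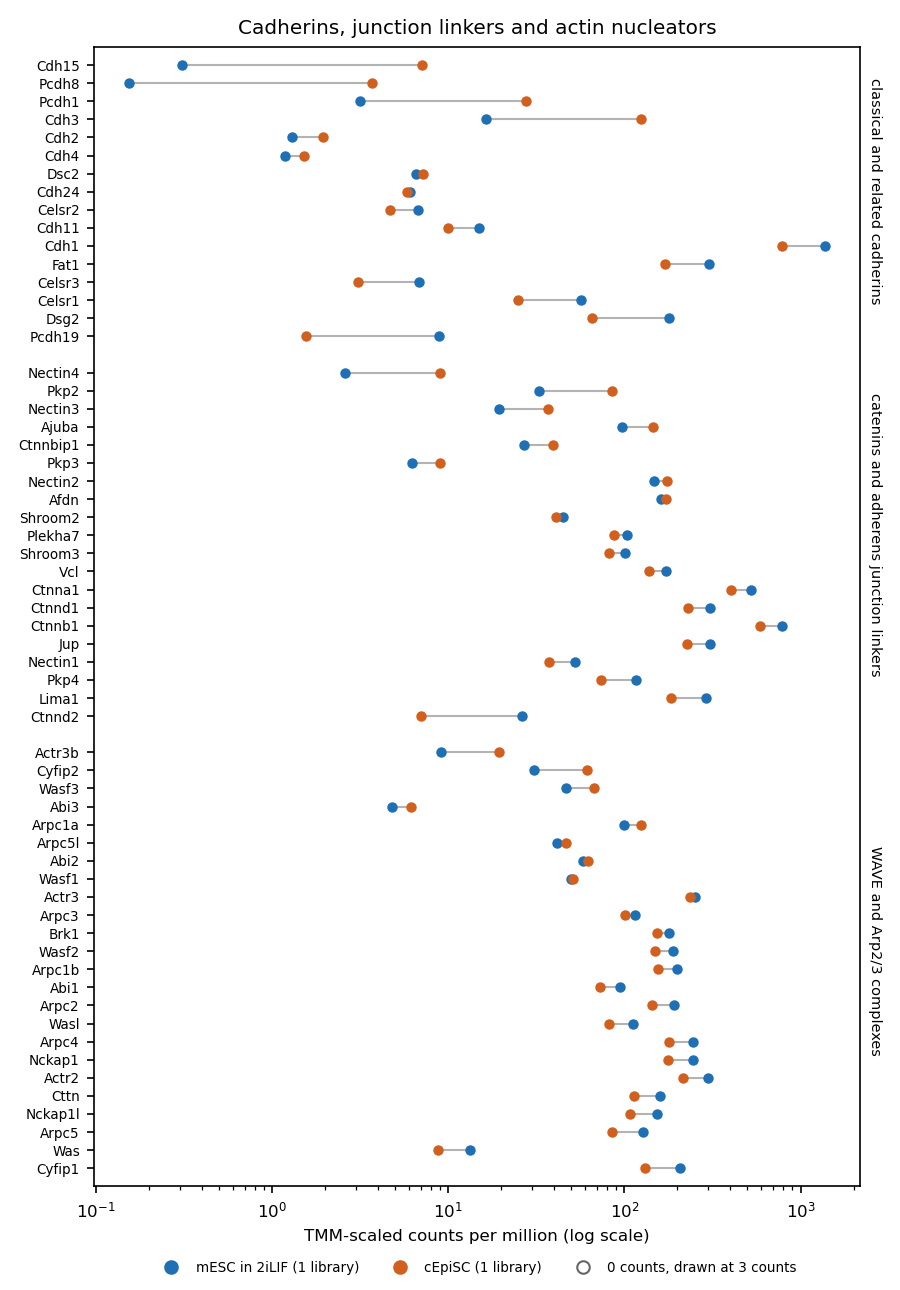
Each line joins a gene's level in the mESC library (blue) and the cEpiSC library (orange), as TMM-scaled CPM on a log axis, for tested cadherins, junction linkers and members of the WAVE and Arp2/3 complexes. Cdh3 was 7.56-fold higher and Cdh1 1.76-fold lower in cEpiSC, and 22 of the 24 WAVE and Arp2/3 genes lay within 2-fold.

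Genes around Rac split in both directions. Of 43 Rac exchange factors, GAPs and effectors 6 were higher, 7 lower and 30 within 2-fold, at a median of -0.22 (-0.34 to -0.18), and at percentile 3.58, or 34.6 with lists also matched on length. With a filter at 5 CPM the median was -0.44, at percentile 0.07. Elmo1, part of an exchange factor complex for Rac, was 4.31-fold higher (7.18 to 30.9 CPM, 2.09 [1.84 to 2.38]). The other genes at the top of that list had few counts, with 1 and 25 for Dock10 (3.12 [1.95 to 9.92]), 3 and 25 for Arhgap25 (2.37 [1.27 to 5.35]) and 5 and 24 for Vav3 (1.83 [0.76 to 3.93]). Lower members, named after their values were seen, included the exchange factor genes Tiam1 (60.2 to 25.8 CPM, -1.22), Dock1 (99.5 to 45.8 CPM, -1.12) and Plekhg1 (142.6 to 63.1 CPM, -1.17), which after centring on length were within 2-fold at -0.90, -0.80 and -0.86. Of the other lower members, Farp1 (-1.01) also came within 2-fold, at -0.86. Elmo3 (-1.26), Srgap1 (-1.33) and Arhgap15 (-1.08) stayed at least 2-fold lower after centring, at -1.24, -1.01 and -1.11. Of 29 genes of actin turnover and membrane linkage 5 were higher, 3 lower (Cap2, 12.3 to 4.01 CPM, -1.59; Gsn, 31.9 to 14.6 CPM, -1.12; Wdr1, 179 to 88.7 CPM) and 21 within 2-fold, at a median of -0.20 (-0.24 to -0.14), a mean of 0.02 and percentile 13.3. Coro2a (0.568 to 13.9 CPM, 4.39 [3.75 to 5.63]) and the thymosin beta-4 gene Tmsb4x (22.9 to 77.6 CPM, 1.75 [1.61 to 1.91]) were the higher members with the highest ratios, and Twf2 (41.8 to 84.4 CPM), Coro1a (1.29 to 2.83 CPM) and Pfn2 (10.2 to 21.6 CPM) the others.

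Extracellular matrix genes had a low median, while the collagen IV genes Col4a1 and Col4a2 were higher. Of 18 tested genes 9 were at least 2-fold lower, 5 higher and 4 within 2-fold, and the median of -0.71 (-0.74 to -0.67) lay below all random lists, and at percentile 0.14 with lists also matched on length. The size of that median varied with the settings, from -0.40 after centring on length or with FPKM and -0.43 without the low filter to -1.17 with a filter at 5 CPM. Lama1, the laminin alpha-1 gene, went from 181 to 10.3 CPM (-4.13 [-4.35 to -3.94]), the nidogen gene Nid1 from 521 to 80.3 CPM (-2.70 [-2.77 to -2.62], with shared reads) and the fibronectin gene Fn1 from 2083 to 654 CPM (-1.67 [-1.70 to -1.64]). Higher members were Col4a1 (9.35 to 61.1 CPM, 2.70 [2.48 to 2.94]), Col4a2 (5.22 to 24.8 CPM), Col18a1 (97.2 to 574 CPM), Lamb1 (75.6 to 153 CPM) and Thbs1 (6 and 65 counts, 3.00 [2.16 to 4.85]). Of 23 integrin and focal adhesion genes 4 were higher, 1 lower and 18 within 2-fold, at a median of -0.13 (-0.21 to -0.03), a mean of 0.23 and percentile 27.1, and the median was 0.01 after centring on transcript length. The adaptor gene Bcar1, which encodes p130Cas, was 4.26-fold higher (47.1 to 201 CPM, 2.09 [1.99 to 2.19]), Itga9 had 19 and 166 counts (2.92), Itga1 3 and 51 (3.34) and Itga8 9 and 45, while Tns1 went from 132 to 19.4 CPM (-2.77 [-2.93 to -2.62]). The list of epithelial-mesenchymal transition genes went both ways: 3 of 14 were higher (Mmp2, 8.73 to 64.7 CPM, 2.87; the epithelial splicing regulator gene Esrp1, 2.12 to 22.4 CPM, 3.34; Twist1, 1.60 to 3.76 CPM), 2 lower (Fn1; Esrp2, 16.6 to 6.69 CPM, -1.30) and 9 within 2-fold. Its median was -0.50 (-0.57 to -0.20), its mean 0.11 and its percentile 1.02, or 1.71 with length matched, but without the low filter the median was -0.04, at percentile 22.4. The list holds both epithelial and mesenchymal genes, so its median gives no direction of a transition.

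**Figure D3:**
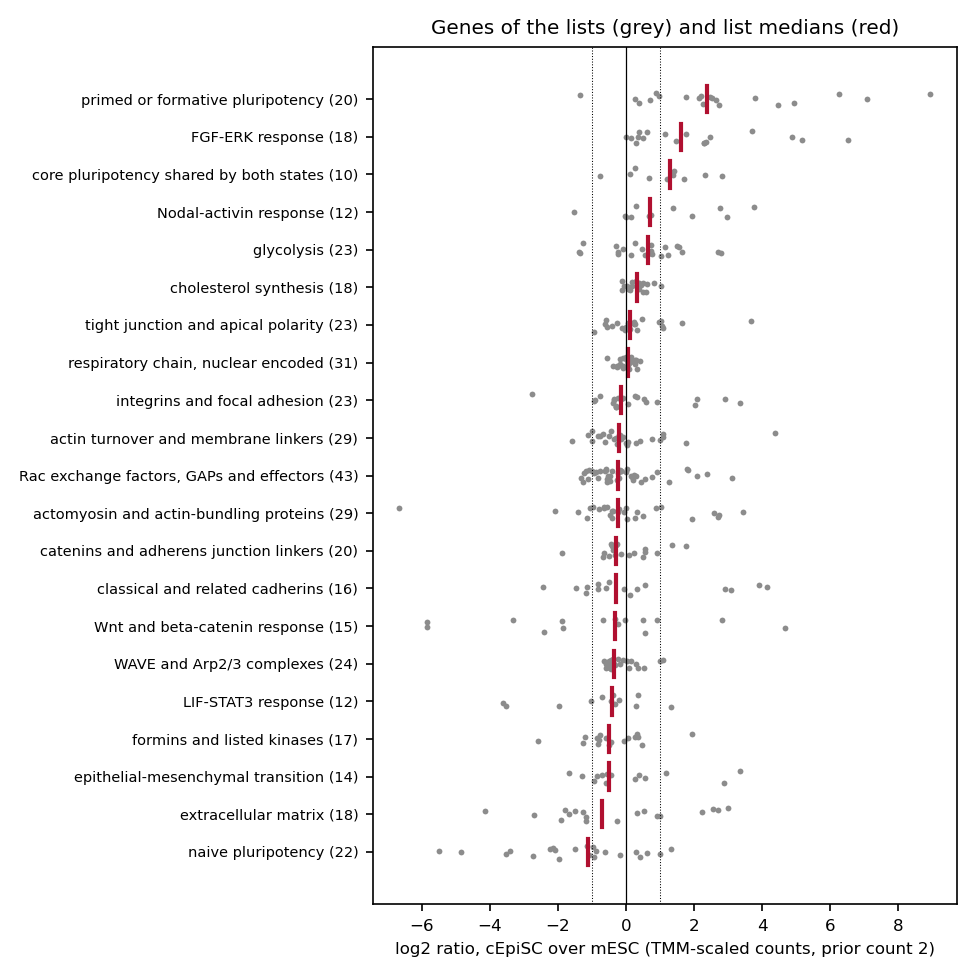
Grey points show the log2 ratio of cEpiSC over mESC (TMM-scaled counts, prior count of 2) for each tested gene of 21 lists, red bars show list medians, dotted lines mark 2-fold, and the number of tested genes follows each name. Medians ran from 2.38 for the primed list to -1.12 for the naive list, and those of the actin and adhesion lists lay between 0.11 and -0.49.

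Markers of differentiated lineages and of other cell types showed no common direction, and many had only a few counts. Of 9 tested primitive streak and mesendoderm genes 4 were lower, 1 higher and 4 within 2-fold, at a median of -0.69 (-0.93 to -0.45) and percentile 1.58, but the median was -0.05 without the low filter, at percentile 8.34, and -0.35 with a filter at 5 CPM, at percentile 17.4. Gsc went from 264 to 6 counts (-5.13 [-7.00 to -4.40]), Wnt3a from 32 to 5 (-2.35), Mixl1 from 26 to 5 (-2.07), brachyury (T) from 2.07 to 0.489 CPM, and Wnt3 from 12 to 55 counts (1.95). Neuroectoderm genes gave 2 higher, 2 lower and 3 within 2-fold of 7 tested, with a median of -0.81 (-0.99 to -0.49), a mean of 0.09 and percentile 1.09, but the median was 0.57 without the low filter, at percentile 85.1. Tubb3 (69.7 to 25.9 CPM, -1.42) and Nes (25.9 to 11.9 CPM, -1.12) were lower, Pax6 (2 and 33 counts, 3.07 [2.00 to 7.07], with shared reads) and Olfm1 (131 and 295 counts, 1.08) higher. Extraembryonic endoderm genes were split, with 2 of 7 higher (Cubn, 5 and 59 counts, 3.06; Foxq1, 5 and 55 counts, 2.96), 2 lower (Dab2, 59.8 to 16.6 CPM, -1.84; Gata4, 8.79 to 4.30 CPM, -1.014, which fell short of 2-fold under 6 of the other settings) and 3 within 2-fold, at a median of 0.46 and percentile 53.2. Of 6 trophoblast genes 4 were higher (Esx1, 7.18 to 38.9 CPM, 2.42; Hand1, 3 and 38 counts, 2.94; Gata3, 18 and 60 counts, 1.56; Ascl2, 27 and 80 counts), 1 lower (Tfap2a, 17.9 to 3.13 CPM, -2.48) and 1 within 2-fold, at a median of 1.49 and percentile 94.5. Fibroblast or feeder genes gave 1 higher (Thy1, 21 and 94 counts, 1.98), 1 lower (Pdgfrb, 12.6 to 5.86 CPM, -1.09) and 3 within 2-fold of 5 tested, at a median of 0.13 and percentile 43.9. Of 9 Hox genes 3 were lower (Hoxc4, 12.1 to 2.10 CPM, -2.48; Hoxb4, 45 and 7 counts, -2.45; Hoxd4, 31 and 8 counts, -1.79), 2 higher (Hoxd1, 5 and 23 counts, 1.77; Hoxa5, 7 and 28 counts) and 4 within 2-fold, at a median of -0.79 and percentile 2.31. Genes of the 2-cell embryo stage gave 4 higher and 1 within 2-fold of 5 tested: Zscan4f had 0 and 62 counts (at least 19.5-fold), Zscan4b 0 and 21 (at least 6.62-fold), Zscan4c 1 and 24 (3.06 [1.89 to 9.87]) and Usp17la 4 and 24 (2.05 [0.96 to 4.49]). These 4 genes passed the filter through cEpiSC alone, and 8 of 13 matched genes fell below it. The Zscan4 copies share reads, and the median of 3.06 (2.73 with bounds) lay at percentile 97.0. Random lists matched on expression were themselves above 0, with a median of 1.38 here, 0.38 for trophoblast and 0.96 for Hox genes. Counts of higher genes in such lists of low abundance are therefore raised by the filter. The median of the 2-cell list ranged from 0.70 with FPKM and 0.88 with TPM to 3.96 with a prior count of 0.5, and was 2.17 without the low filter, at percentile 99.98.

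Glycolysis genes were higher as a group and respiratory chain genes were not. Of 23 glycolysis genes 8 were at least 2-fold higher, 3 lower and 12 within 2-fold, and the median of 0.66 (0.64 to 0.68) lay above all random lists. The lactate exporter gene Slc16a3 went from 40.7 to 285 CPM (2.802 [2.70 to 2.91]), Pdk1, whose kinase restrains pyruvate entry into mitochondrial oxidation, from 66.4 to 430.0 CPM (2.69 [2.61 to 2.78]), Eno3 from 5.89 to 18.8 CPM (1.66) and the glucose transporter gene Slc2a1 from 301 to 884 CPM (1.55 [1.51 to 1.60]). The lower members were Hk1 (345 to 134 CPM), Hk2 (355 to 139.8 CPM) and the glucose transporter gene Slc2a3 (3087 to 1302 CPM). All 31 nuclear genes of the respiratory chain lay within 2-fold, at a median of 0.05 (0.02 to 0.07) that became -0.09 after centring on length, and at percentile 91.8. Atp5b stood at 2254 and 2322 CPM (0.04, but -0.00 with TPM and -0.02 after centring on length) and Atp5a1 at 1239 and 1334 CPM (0.11). Cholesterol synthesis genes gave 1 higher (Lss, 88.2 to 182 CPM, 1.04 [0.96 to 1.13]) and 17 within 2-fold, with a median of 0.34 (0.29 to 0.38) above all random lists.

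Among stress and growth lists, the 14 stress and unfolded protein response genes had 3 lower, 2 higher and 9 within 2-fold, at a median of -0.50 (-0.54 to -0.42) and percentile 0.59. Ddit3 went from 23.0 to 5.18 CPM (-2.13), the asparagine synthetase gene Asns from 1565 to 594 CPM (-1.40 [-1.43 to -1.37]) and Trib3 from 64.8 to 30.8 CPM, while Gadd45a went from 12.9 to 119 CPM (3.20 [3.02 to 3.40]) and Hspa1a from 24 to 65 counts (1.29, with shared reads). Of 12 p53 targets 2 were higher (Pmaip1, 16.2 to 74.3 CPM, 2.19; Bbc3, 39.6 to 81.7 CPM, 1.04), 1 lower (Trp53inp1, 232 to 113 CPM, -1.04) and 9 within 2-fold, at a median of 0.38 (0.32 to 0.45) and percentile 99.95. Of 19 cell cycle regulators 3 were higher (Cdkn1c, 11 and 143 counts, 3.41; Ccnd2, 8 and 49 counts, 2.28; Cdkn2b, 9.10 to 19.8 CPM, 1.12) and 16 within 2-fold, at a median of 0.07 and percentile 81.8. Of 13 genes often used as references 11 lay within 2-fold, at a median of 0.01 (-0.05 with TPM) and percentile 69.4, but Pgk1 was higher (494 to 1167 CPM, 1.24 [1.21 to 1.28]) and B2m lower (45.0 to 20.9 CPM, -1.10 [-1.28 to -0.94]). Hprt, also on that list, had only 3 and 8 counts and was singled out after its value was seen, and E14TG2a is known as a line without working Hprt.

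Transcript length went along with the ratio in these libraries. The median log2 ratio went from 0.17 in the shortest decile of tested genes to -0.32 in the longest, where 160 genes were at least 2-fold higher and 209 lower. Across 9787 genes at 10 CPM or more, which are not independent replicates, the Spearman correlation of the ratio with transcript length was -0.23 (-0.25 to -0.21 over 100 resamples of genes). After centring on the median of each length decile, an alternative chosen after seeing the data, 1832 genes were at least 2-fold higher and 1126 lower. Of 250 list entries past 2-fold, 25 came within it, of which 20 had been lower, among them Stat3 and Wdr1. These entries count a gene once per list and include the 7 lists chosen after the data were seen. Of 35 lists fixed in advance that had values, 9 lay below and 8 above the central 95% of random lists. Lists of independently drawn genes would lie outside in about 5% of cases. Genes of a list can vary together and some lists share genes, so 5% is not the rate expected between cultures of the same state. With random lists also matched on length 16 of those 17 stayed outside, the exception being the formin list, whereas after centring on length the exception was the neuroectoderm list, at percentile 3.41. Without the low filter 14 stayed outside, with the neuroectoderm, primitive streak and epithelial-mesenchymal transition lists inside. With a filter at 5 CPM 15 stayed outside, since the primitive streak list moved inside and the Hox list kept only 2 tested genes and has no percentile, while the Rac regulator (percentile 0.07), actomyosin (0.46) and cadherin (1.08) lists also lay below the central range. Actomyosin did so after centring on GC content too (1.25).

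**Figure D4:**
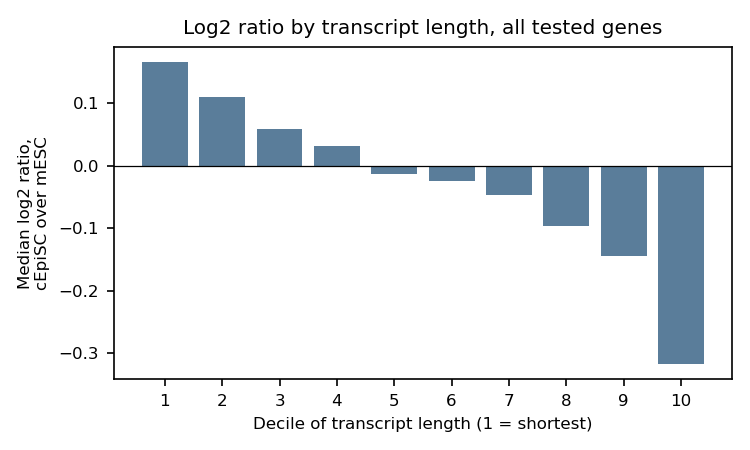
Bars show the median log2 ratio of cEpiSC over mESC for tested genes in 10 groups of equal size by transcript length, from the shortest (1) to the longest (10). The medians went from 0.17 to -0.32.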

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

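No paired analysis was possible because each state has 1 library, and for the same reason no replicate could be left out. The planned pseudocount of 0.1 was not run, as it applied only to data without counts. Ratios centred on length or GC content were chosen after seeing the data. Against 1796 higher and 1225 lower genes, the higher count was 2712 without a filter (16854 genes tested), 970 with a filter at 5 CPM (11046 tested), 1092 with TPM and 945 with FPKM, and the lower count was 680 with FPKM. The remaining higher counts lay between 1715 and 1933 and the remaining lower counts between 924 and 1665, and with DESeq2 size factors 1796 of the higher and 1219 of the lower calls were kept. Library totals alone shifted the median of all genes by 0.07 and moved list medians to -1.05 (naive), 1.37 (core), -0.21 (catenins), -0.14 (Rac regulators), -0.27 (WAVE and Arp2/3) and -0.41 (formins). FPKM gave -1.03 (naive), 1.97 (primed), 1.35 (core), -0.063 (cadherins), -0.20 (catenins), -0.15 (Rac regulators), -0.27 (WAVE and Arp2/3) and -0.40 (formins), and TPM gave 2.04 (primed), 1.24 (core) and -0.39 (WAVE and Arp2/3). Without a filter, the actomyosin median was -0.13, and at 5 CPM -0.58 (cadherins), -0.44 (Rac regulators) and -0.39 (actomyosin). Centring on length gave -0.048 (catenins) and -0.13 (Rac regulators), and centring on GC -0.27 (WAVE and Arp2/3). Reversed in sign were neuroectoderm without a filter (0.57) and axon guidance without a filter (0.38) and centred on length (0.027). Medians inside the percentile edges also changed sign: without a filter cadherins (0.21), at 5 CPM extraembryonic endoderm (-1.01), trophoblast (-0.03) and fibroblast genes (-0.48), centred on length integrins (0.01) and the respiratory chain (-0.09), and with TPM the reference genes (-0.05). Fewer or more genes tested account for the changes under the filters; for the others the cause was not tested. Of 156 named genes past 2-fold, 32 lost that size with TPM and 45 with FPKM. The pseudocount shrinks low genes there, but Lss, at 40.6 and 69.9 TPM, was not low and still came to 0.77 with TPM, and the cause was not tested. On centring by length 9 lost it (Nes, Gata4, Pdgfrb, Cit, Fmn1, Tet2, Bbc3, Trp53inp1, Vldlr). With library totals 4 did (Gata4, Tet2, Trp53inp1, Rpl10l), with a prior count of 5 2 did (Gata4, Marveld3) and on centring by GC 2 did (Gata4, Rpl10l). Only Rac1 and Atp5b changed sign.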

Other observations

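In this part, 7 gene lists were chosen after the values of other genes had been seen, and so were the tests of leftover cells and of centring on length or GC content. Among genes of protein synthesis, the ribosomal protein list had a median above 0 and the aminoacyl-tRNA synthetase list a median below 0, with nearly all members within 2-fold. Of 83 ribosomal protein genes 82 lay within 2-fold, yet 75 were above 0, and the median log2 ratio of 0.27 (0.26 to 0.28) lay above all random lists and at percentile 99.9 with lists also matched on length, although the median was only 0.11 after centring on length. The exception past 2-fold was Rpl10l, a retrogene also on the germline list (106 to 51.8 CPM, -1.03). All 20 cytosolic aminoacyl-tRNA synthetase genes lay within 2-fold and 18 were below 0, at a median of -0.42 (-0.44 to -0.38) and percentile 0.45. The most abundant were Aars (1012 to 526 CPM, -0.94 [-0.98 to -0.91]) and Gars (836 to 694 CPM, -0.27 [-0.30 to -0.24]). Genes of the amino acid starvation response gave 3 lower (Asns, 1565 to 594 CPM; Nupr1, 67.5 to 31.4 CPM, -1.10; Vldlr, 146 and 71 counts, -1.10), 1 higher (the arginine transporter gene Slc7a3, 67.4 to 160.0 CPM, 1.25) and 16 within 2-fold, at a median of -0.30 and percentile 4.79.

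Imprinted genes had a high median with members on both sides of 0. Of 21 tested genes 12 were above a log2 ratio of 0 and 9 below, and 8 were at least 2-fold higher, 1 lower and 12 within 2-fold, at a median of 0.64 (0.31 to 0.69) and percentile 99.96. Peg10 went from 121 to 698 CPM (2.53 [2.46 to 2.59]), Nnat from 23 to 217 counts (3.05) and Igf2 from 4 to 32 counts (2.44), whereas Plagl1, a zinc finger gene known to regulate other imprinted genes, went from 196 to 5.77 CPM (-5.06 [-5.36 to -4.82]). Guidance cues split: of 36 axon guidance genes 12 were higher, 6 lower and 18 within 2-fold, at a median of -0.28 and percentile 0.93, or 4.74 with length matched, but that median was 0.38 at percentile 89.6 without the low filter and 0.03 at percentile 23.2 after centring on length. The secreted cue genes Slit2 (704 and 16 counts, -5.37 [-6.36 to -4.83]) and Ntn1 (610 and 17 counts, -5.09 [-6.04 to -4.55]) and Rgma (539 and 24 counts, -4.46 [-5.22 to -3.98]) were lower, and the receptor gene Robo4 higher (12 and 402 counts, 4.78 [4.16 to 5.95]). Of 17 Eph receptors and ephrins 5 were higher, 4 lower and 8 within 2-fold, at a median of -0.35 and percentile 3.11. Among them Efnb2 (3.77 to 34.9 CPM, 3.18), Epha7 (2.84 to 10.8 CPM, 1.88) and Epha8 (0 and 44 counts, at least 13.9-fold) were higher and Epha4 lower (103 to 15.0 CPM, -2.77 [-2.96 to -2.60]). Chromosome medians of the ratio at 10 CPM or more ran from -0.13 on chromosome 11 to 0.06 on X, apart from 4 genes on Y at -0.39.

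When the low medians of the actin and matrix lists were set against random lists matched on transcript length, WAVE and Arp2/3 stayed at percentile 1.06, extracellular matrix at 0.14 and epithelial-mesenchymal transition at 1.71. For WAVE and Arp2/3 and the transition list this argues against length as the whole cause. Matrix genes had a median length of 5.84 kb, and the longest bin spanned 5.86 to 82.6 kb. Matching could not remove a length effect within that bin, and the matrix median shrank to -0.40 when centred on length. Formins moved to 5.22 with length matched, as a length effect would give, but stayed at -0.44 and percentile 0.71 when centred on length, so length as a cause remains open for them. With GC content matched, WAVE and Arp2/3 lay at 1.19, extracellular matrix at 0.01, the transition list at 1.11 and formins at 0.73. This argues against GC content as the whole cause, although centring on GC put WAVE and Arp2/3 at 4.22. Without the low filter the transition list was no longer low (-0.04, percentile 22.4). The trend itself followed transcript length within deciles of genomic span (-0.23) and not genomic span within deciles of transcript length (0.07), as a difference in RNA integrity or fragment recovery could produce. A true shift away from long transcripts between the states would look alike in 1 library each and remains open, as does a biological difference between the states for the lists that stayed low.

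Nanog, Zfp42, Esrrb and Klf4 kept between 25.6% and 54.7% of their mESC level in cEpiSC. One hypothesis was that unconverted mESCs remained in the culture and carried these transcripts. Such cells would bring all their abundant naive transcripts, yet 3 of 16 naive genes at 100 CPM or more in mESC (Tfcp2l1, Tbx3 and Jam2) had upper limits below a level of 50% of the Klf4 ratio. The lowest of these limits was 4.03% of the mESC level, for Jam2. This argues against leftover cells with the full mESC profile as the source of the levels kept by Nanog, Zfp42, Esrrb and Klf4, but a small share of such cells is not excluded. The profile of unconverted cells after 2 days in the new medium was not measured, so leftover cells that had lost the transcripts of Tfcp2l1, Tbx3 and Jam2 stay open. A slower or incomplete decline of these genes within converting cells stays open and was not tested, as there is 1 time point.

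Glycolysis genes lay above all random lists with length matched as well (percentile 100), which argues against length as the cause. A second hypothesis was a response of the hypoxia type in the converted cells. Of 23 hypoxia targets outside the glycolysis list 7 were at least 2-fold higher, 1 lower and 15 within 2-fold, at a median of 0.44 (0.33 to 0.57) and percentile 99.81 with or without length matched, which is consistent with it. Egln3 (4.03 to 42.2 CPM, 3.36), Bnip3 (18.6 to 166 CPM, 3.15), Car9 (23 and 95 counts, 1.88) and Fam162a (24.5 to 72.0 CPM, 1.55) were higher, but Vegfa, a central target, was lower (50.4 to 19.4 CPM). Oxygen, cell density and the change of state itself could each underlie the pattern, and these libraries do not separate them.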
